A study of Rattus norvegicus with 8 samples.

How the data were processed

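Small RNA libraries of rat placenta were compared between dams given the flame retardant BDE-209 (decabromodiphenyl ether) and dams given the corn oil vehicle. Per the labels, RNA was extracted with a mirVana kit, which keeps small RNAs, and libraries were made with a NEBNext small RNA kit. The trimming, the aligner, the microRNA database release, the genome build and the treatment of reads that match several microRNAs are not given in the sources used here. The samples were grouped by their titles and dose labels into 4 control and 4 BDE-209 libraries, and libraries are named here by group and replicate number. The labels do not say whether the 4 libraries of a group came from separate dams or litters, so p-values measure the spread between these samples, which may be partly technical.

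The authors deposited 1 table of 990 microRNAs, of which 753 carry names of known rat microRNAs and 237 are candidate microRNAs predicted by the authors' processing. The deposited count columns hold whole, unnormalised read counts per microRNA, 8 columns for 8 libraries, per the file headers. The deposited TPM columns, so named per the file headers, equalled each count divided by its column total and scaled to a fixed sum per library, with a largest difference of 0.000477, so they hold no length term. The TPM columns were therefore not tested. Of the 990 microRNAs, 168 had 0 counts in each library, 30 of them predicted. No predicted microRNA had a count from 1 to 9 in any library, whereas 733 such values occurred among the known ones, so the predicted counts read as subject to a minimum of 10 and a listed 0 there is not a measured absence. A further 118 predicted microRNAs had the same nonzero counts as another predicted one. Predicted microRNAs held 0.0187% to 0.0386% of the counts of a library. Total counts ranged from 7392692 to 16971083 per library. Where a known microRNA was counted, a count of 0 allows up to 3 counts, or 0.177 to 0.406 counts-per-million (CPM) depending on the library. The libraries carry no molecular identifiers, so such limits cover counting error only.

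The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling factors, the default filterByExpr filter (minimum count 10, minimum total 15) by group, group as the sole term, and Benjamini-Hochberg adjustment with a threshold of 0.05. TMM factors ranged from 0.633 to 1.22 and differed between the groups. They were 1.01 to 1.22 in controls, 0.927, 0.816 and 0.633 in BDE-209 libraries 1 to 3, and 1.20 in BDE-209 library 4. The filter kept 541 microRNAs, 467 known and 74 predicted. Levels are CPM scaled by the TMM factors, given as mean ± SD over 4 libraries, and log2 fold changes are BDE-209 over control with their standard error (SE). Fold changes are relative to this scaling, under which the median log2 fold change of the tested microRNAs was -0.07. It was -0.44 when libraries were scaled by total counts alone, and 0.03 with upper-quartile scaling.

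Before the data were examined, 23 lists of microRNAs were fixed from general knowledge: genomic clusters and families of placenta and growth control, a mixed list of microRNAs reported in hypoxic or insufficient placenta, and markers of other cell types. Lists were filled by name with any arm of a hairpin, so family lists also hold opposite arms, which have other seeds. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over 20 lists. Where stated, the edgeR p-values of members were also adjusted over their list alone. That adjustment was not in the plan fixed before the data were examined and does not correct over lists. Members said to rise or fall over a list alone are thus not calls of the main test, unless also named as such. The share of all counts taken by each list was compared by an exact two-sided permutation test over the 70 assignments of the 8 libraries, for which the smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over 22 lists. The microRNAs named were fixed by a rule written before the data were examined. The rule took up to 12 that rose and 12 that fell with the smallest p, the 10 with the highest mean share of counts, the 2 members of each list with the smallest p and the 2 with the highest mean, and miR-210, miR-21, miR-122 and miR-451. Predicted microRNAs were tested and counted but not named.

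The edgeR step was tested on simulated data for the comparison of BDE-209 with control, in 5 data sets of 541 microRNAs of which 200 were changed. The filter kept 517 in the first data set. Among those kept, the edgeR step recovered 58.3% of those changed 2-fold and 97.1% of those changed 4-fold, with 2.50% of calls false. In 10 simulated data sets without change it made 0.2 calls on average. The simulated libraries of a group shared the same expected levels, so a library lying apart from its group was not simulated. Pairs of libraries within a group differed far beyond counting noise, with chi-square per degree of freedom from 756 to 4368, so no pair was treated as 1 library deposited more than once. This does not show that the libraries came from separate animals.

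Alternatives planned before the data were examined were DESeq2 size factors, total-count and upper-quartile scaling, no filter on low counts, a mean of at least 10 CPM, a block for the replicate number, limma-voom, robust edgeR fitting, the Wald test of DESeq2 1.42.0, collapsing identical predicted microRNAs, and leaving out each library in turn. Settings planned for a table of normalised values alone were not needed, since counts were present. Added after seeing the data were library sizes without the most abundant microRNA, known microRNAs alone, counts thinned to the smallest library, and limma-voom with sample weights. Hairpins were placed in genomic order with RefSeq genes of the assembly GRCr8, which was used for names and for neighbourhood alone and matched 752 of the 753 known names. No microRNA sequences were used, so base composition and cross-mapping between near-identical microRNAs were not tested. Exact and resampling tests were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.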

Results

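MicroRNAs, short RNAs that repress messenger RNAs with matching sites, were counted in placentas of Sprague-Dawley rats at gestational day 20. BDE-209 is a fully brominated diphenyl ether used as a flame retardant. Per the labels, 16 pregnant rats received corn oil or 500 mg/kg/day BDE-209 by gavage, 8 per group, for 20 days from gestational day 0, and placentas were taken 4 h after the last dose. The comparison asks whether this exposure altered the placental microRNA profile. The table holds 4 control and 4 BDE-209 libraries. Control libraries 1 to 4 held 16971083, 10862674, 15094673 and 13908503 counts, and BDE-209 libraries 1 to 4 held 10765700, 7392692, 11636989 and 12628336. The mean depth was 14209233 ± 2562662 counts in controls and 10605929 ± 2273297 after BDE-209 (SD, n = 4 each, exact two-sided permutation p = 0.0857). Known microRNAs with at least 1 count numbered 564 to 573 in controls and 528 to 566 after BDE-209 (n = 4, exact permutation p = 0.0571), and 549.25 ± 7.14 against 534.75 ± 15.2 (SD, exact permutation p = 0.143) after thinning each library to the smallest total.

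The 10 most abundant microRNAs of each library held 44.8% ± 3.07 of its counts in controls and 50.3% ± 5.21 after BDE-209 (SD, n = 4). miR-148a-3p, which targets the DNA methyltransferase Dnmt1, had the highest mean share. It took 6.70% of counts in controls and 14.3% after BDE-209, and its log2 fold change of 1.62 ± 0.49 (SE) missed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0699). Its share differed between the exposed libraries, at 10.9%, 16.1%, 22.8% and 7.57% in BDE-209 libraries 1 to 4. miR-127-3p, which is transcribed opposite the imprinted gene Rtl1 required for fetal capillaries of the placenta, averaged 58818 ± 11031 CPM in controls and 87028 ± 20829 CPM after BDE-209. Its unscaled share of counts was 6.74% and 7.46%, so the size of this difference depends on the TMM scaling. The other abundant microRNAs were miR-7a-5p, miR-26a-5p, miR-143-3p, miR-450a-5p, miR-293-5p, let-7i-5p, let-7g-5p and let-7f-5p, with log2 fold changes from -0.11 to 0.61. Adjusted p-values of these 8 and of miR-127-3p lay at 0.136 or above (edgeR quasi-likelihood, Benjamini-Hochberg).

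BDE-209 libraries 1 to 3 separated from the controls along the leading principal component, which held 50.03% of the variance, with scores from 6.89 to 18.3 against -14.8 to -5.80 in controls. BDE-209 library 4 had a score of -4.55, beside the controls. Its mean correlation of log2 CPM across microRNAs was 0.986 with the controls and 0.970 with the other exposed libraries. Each other library correlated better with its own group, by a small margin for BDE-209 library 1 (0.975 against 0.973 with the controls).

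**Figure D1:**
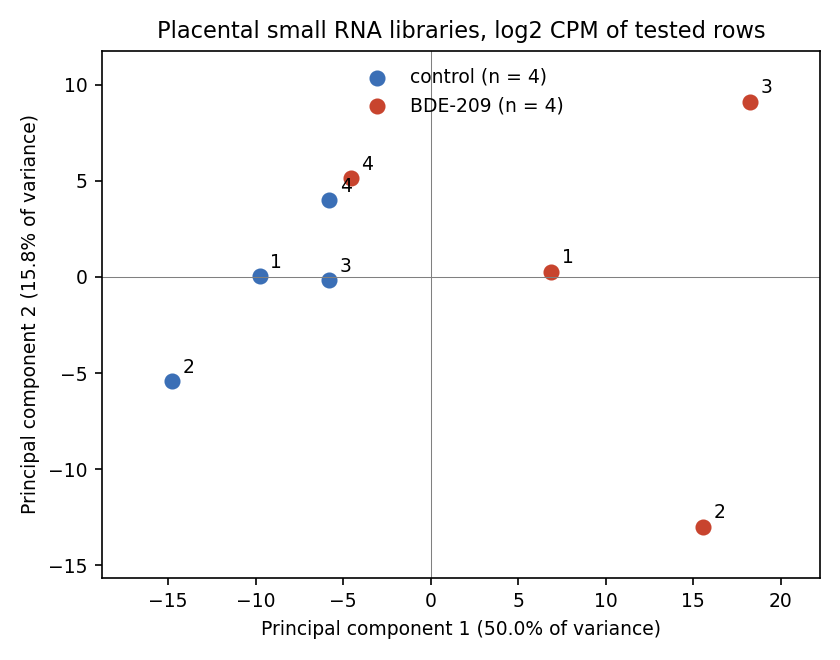
Principal components of log2 CPM of the tested microRNAs, 1 point per library, numbered by replicate, with the percent of variance on each axis. Blue points are the 4 controls and red points the 4 BDE-209 libraries, of which library 4 lies at -4.55 on the horizontal axis, next to the controls.

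After BDE-209, 8 microRNAs rose and 15 fell, among them the cell-cycle regulators miR-322-5p, miR-503-5p and miR-16-5p, the collagen regulators miR-29a-3p and miR-29c-3p, and the proliferation-linked miR-19b-3p and miR-106b-5p. The rises ranged from 1.86-fold to 3.44-fold and the falls of the 14 known microRNAs from 1.99-fold to 5.14-fold, the last for miR-9a-3p, which rests in part on 1 control library. miR-151-3p, which lies in an intron of the focal adhesion kinase gene Ptk2, rose from 2655 ± 479 to 8474 ± 4799 CPM (log2 fold change 1.67 ± 0.38, SE). miR-543-3p of the imprinted Dlk1-Dio3 cluster rose from 6062 ± 1763 to 17929 ± 9264 CPM (1.56 ± 0.37). The other rises were miR-1247-5p (log2 fold change 1.78), miR-6329 (1.56), miR-409a-3p (1.40), miR-3559-3p (1.29), miR-676 (1.20) and miR-485-3p (0.89). Among the abundant microRNAs that fell, miR-322-5p went from 9262 ± 731 to 4659 ± 649 CPM (log2 fold change -0.99 ± 0.20), miR-503-5p from 7450 ± 1954 to 2570 ± 1293 CPM (-1.54 ± 0.35) and miR-374-5p from 3988 ± 1062 to 1517 ± 424.1 CPM (-1.39 ± 0.28). miR-9a-3p, which acts in neural progenitors, fell from 46.1 ± 41.6 to 8.93 ± 1.84 CPM (log2 fold change -2.36 ± 0.53). Control library 4 held 106.5 CPM of it, and without that library the log2 fold change was -1.53 and missed the threshold (edgeR adjusted p = 0.0800, Benjamini-Hochberg). miR-883-3p (-1.68), miR-883-5p (-1.44), miR-540-5p (-1.30) and miR-154-3p (-1.21) also fell. miR-3551-3p (-1.98, and -2.78 without BDE-209 library 4, which held 96 counts against 22, 12 and 7 in libraries 1 to 3) fell too and is named although the rule did not take it, after its values were seen. The remaining fall was a predicted microRNA with 20, 10, 17 and 24 counts in controls and a listed 0 in each exposed library, for which no fold is given because its counts appear to have a minimum.

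Among the microRNAs tested by the edgeR quasi-likelihood test, these 23 had Benjamini-Hochberg adjusted p-values from 0.0475 to 0.0485, just inside the threshold. At an unadjusted p under 0.05 there were 171, with 85 higher and 86 lower, where 27.1 would come by chance. In 21 of the 23 the libraries of the groups did not overlap, as in 94 of all tested, where chance gives 2.86%, or 15.5. Upper-quartile scaling gave 31 calls, 17 that rose and 14 that fell. Leaving out BDE-209 library 4 gave 67 that rose and 66 that fell, including each of the 23, whereas leaving out any other library gave 0 by edgeR, with 108 to 168 at an unadjusted p under 0.05. On the 8 libraries, total-count scaling and the absence of a filter each gave 0 by edgeR (23 higher and 120 lower at an unadjusted p under 0.05 by total-count scaling, and 111 higher and 100 lower without a filter), robust edgeR fitting gave 4, limma-voom 24 and DESeq2 119.

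**Figure D2:**
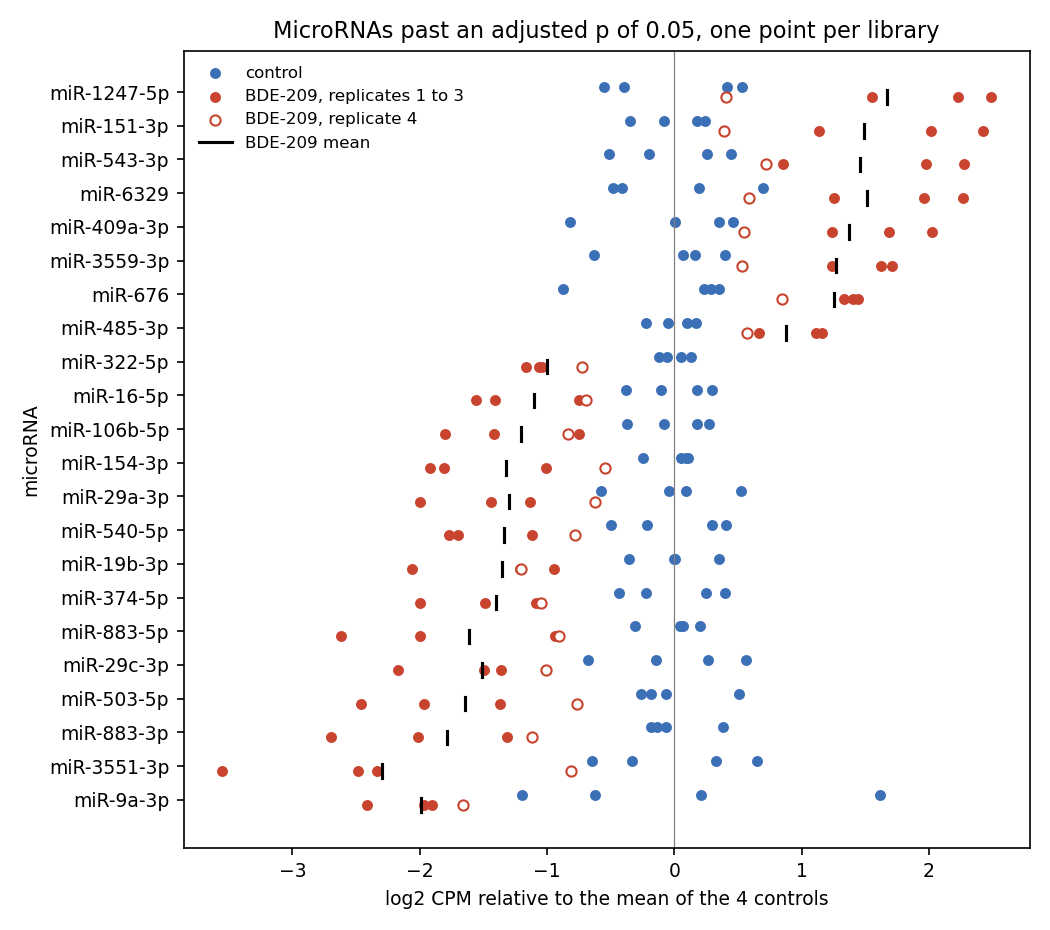
Levels of the 22 known microRNAs past the threshold, as log2 CPM minus the mean of the 4 controls on the horizontal axis, 1 point per library. Blue points are controls, filled red points BDE-209 libraries 1 to 3, open red points BDE-209 library 4 and black ticks the exposed mean. Library 4 lies on the same side of the control mean as the other exposed libraries in each. The microRNAs were chosen by a test that counted library 4 as exposed, which favours this, so it does not show a shared response.

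Of 19 tested members of the miR-17-92 cluster and its paralogs, which promote proliferation, 16 had lower means after BDE-209. The list passed camera at its preset correlation (Benjamini-Hochberg adjusted p = 0.0118) but not with an estimated correlation (p = 0.161, adjusted p = 0.913) or fry for a shared direction (adjusted p = 0.0764). Of its members 2 fell (miR-19b-3p, from 411.4 ± 82.2 to 165 ± 47.9 CPM, and miR-106b-5p, from 428 ± 81.9 to 191.6 ± 62.1 CPM). Their abundant members miR-92a-3p and miR-25-3p had log2 fold changes of -0.37 ± 0.24 and 0.19 ± 0.22, neither past the threshold. Adjusted over the list alone, 7 members fell. Of 20 lists it was the sole one to pass camera, and its call was absent without control library 4 (camera adjusted p = 0.106, Benjamini-Hochberg). By fry for change in either direction, which compares a list with no other microRNAs, 10 of the 20 lists passed, this one among them (adjusted p = 0.0199, Benjamini-Hochberg).

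The miR-15/16 family, which represses cyclins and the survival factor Bcl2, had 6 of 7 members with lower means. miR-16-5p fell from 1335 ± 271 to 633 ± 190 CPM, and miR-15b-5p had a log2 fold change of -0.96 ± 0.34 (edgeR adjusted p = 0.0800, Benjamini-Hochberg). Adjusted over the list alone, 6 fell and miR-195-3p, at 1.24 ± 0.34, rose. Its more abundant partner arm miR-195-5p, at -0.61, was among the 6. In the miR-29 family, which represses collagens, 3 of 5 members had lower means. miR-29a-3p fell from 1797 ± 550 to 747 ± 290.7 CPM and miR-29c-3p from 19.3 ± 6.75 to 6.71 ± 2.08 CPM, while miR-29b-3p had a log2 fold change of 0.44 ± 0.39. Adjusted over the list alone, 3 fell. In the X-linked cluster of miR-322, miR-503 and miR-351 2 of 12 members fell, by either adjustment, and the abundant miR-450a-5p and miR-450b-5p had log2 fold changes of -0.06 ± 0.26 and 0.27 ± 0.30. While miR-322-5p fell, its partner arm miR-322-3p had a log2 fold change of 0.61 (edgeR unadjusted p = 0.0275). They took 0.749% and 0.396% of counts. Camera gave adjusted p-values of 0.150 for miR-15/16, 0.288 for miR-29 and 0.793 for the X-linked cluster (Benjamini-Hochberg). Members of a family from the same arm can differ by a few bases. How the authors' counting divided reads shared between them is not given in the sources used here, so their separate values are uncertain. The family lists also hold opposite arms, to which the function named for a family may not apply.

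The imprinted Dlk1-Dio3 cluster, expressed from the maternal chromosome and abundant in placenta, moved in both directions. Of its 83 tested members 3 rose (miR-543-3p, miR-409a-3p and miR-485-3p, from 188.9 ± 22.03 to 351.05 ± 73.0 CPM), 2 fell (miR-154-3p, from 395 ± 43.5 to 171 ± 78.2 CPM, and miR-540-5p) and 78 did not pass. Adjusted over the list alone, 13 rose and 7 fell. This balance moved with the scaling: at an unadjusted p under 0.05, 19 were higher and 14 lower by TMM, 6 and 16 by total counts, and 24 and 8 by upper quartile. Its camera adjusted p was 0.793, and fry adjusted p-values were 0.668 for a shared direction and 0.0267 for change in either direction (Benjamini-Hochberg), a test that 9 other lists passed too. The abundant miR-379-5p had a log2 fold change of 0.80 ± 0.26 (edgeR adjusted p = 0.0699, Benjamini-Hochberg). Of 20 tested members of the X-linked cluster of male germ cells, miR-883-3p (577 ± 112 to 180 ± 80.3 CPM) and miR-883-5p fell. Its abundant miR-741-3p and miR-871-3p had higher means, with log2 fold changes of 0.92 ± 0.32 and 1.24 ± 0.40. Adjusted over the list alone, 5 of the germ-cell list rose and 7 fell.

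Clusters of the early embryo and trophoblast did not pass camera, while fry for change in either direction gave adjusted p-values of 0.0267 for the miR-290 cluster, 0.838 for the Sfmbt2 cluster and 0.0249 for the list of hypoxia (Benjamini-Hochberg). The miR-290 cluster, active in early embryos and extraembryonic tissue, had 4 of 11 members with higher and 7 with lower means, and 4 fell when adjusted over the list alone. Its miR-293-3p and miR-295-5p had log2 fold changes of -1.30 ± 0.39 and -1.13 ± 0.32, while the abundant miR-292-5p had 0.81 ± 0.36. The Sfmbt2 cluster, enriched in rodent placenta, had 3 tested members, 2 with higher means, and miR-466c-5p, miR-466d and miR-466b-5p had log2 fold changes of -0.39, 0.47 and 0.26. The list of hypoxia and placental insufficiency had 5 of 7 members with lower means. In it the hypoxia-induced miR-210-3p averaged 803 ± 184 CPM in controls and 470 ± 138 CPM after BDE-209 (log2 fold change -0.77 ± 0.26, edgeR adjusted p = 0.0770, Benjamini-Hochberg). miR-155-5p had a log2 fold change of -0.74 ± 0.25 and miR-210-5p of -0.54 ± 0.41, and adjusted over the list alone 2 members rose (miR-195-3p and miR-223-5p) and 2 fell (miR-155-5p and miR-210-3p). The more abundant partner arms of those that rose, miR-195-5p and miR-223-3p, had log2 fold changes of -0.61 and -0.72.

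Further families had no member past the threshold, by edgeR over all tested microRNAs or adjusted over the list alone unless stated. In the let-7 family, which promotes differentiation, 7 of 17 members had higher and 10 lower means, with let-7i-5p at a log2 fold change of 0.56 ± 0.24 and let-7i-3p at -0.60 ± 0.28. The miR-181 family had lower means in each of 7 members, such as miR-181c-3p at -0.70 ± 0.30 and miR-181b-5p at -0.31 ± 0.23. The family of miR-34 and miR-449, in which miR-34a-5p is induced by p53, had 3 of 5 lower, with miR-34a-5p at -1.14 ± 0.42. The miR-30 family had 6 of 9 higher, with miR-30d-5p at 1.05 ± 0.36 and miR-30e-5p at -0.68 ± 0.25. The cluster of miR-183, miR-96 and miR-182 had 3 of 4 higher, with miR-182 at 0.67 ± 0.34. The vascular clusters of miR-23, miR-27 and miR-24 and of miR-221 and miR-222 had 6 of 13 higher, with miR-27a-5p at 0.84 ± 0.28. The epithelial miR-200 family had 3 of 8 higher, and miR-200a-5p, at 1.40 ± 0.37 (edgeR adjusted p = 0.0545, Benjamini-Hochberg), rose when adjusted over the list alone, with miR-200a-3p at -0.50 ± 0.28. The camera directions were up for let-7, the vascular clusters and miR-200, whose medians were -0.02, -0.01 and -0.06 and whose means were 0.03, 0.03 and 0.04.

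Markers of other cell types gave no list past camera, while by fry for change in either direction the leukocyte, neural and germ-cell lists had adjusted p-values of 0.0292, 0.0359 and 0.0267 (Benjamini-Hochberg). The hepatocyte microRNA miR-122-5p averaged 4.26 ± 3.56 CPM in controls and 67.4 ± 88.3 CPM after BDE-209 (log2 fold change 3.98 ± 1.07, edgeR adjusted p = 0.0563, Benjamini-Hochberg), so it did not pass. As the sole tested member of its list it had no adjustment over the list alone (edgeR unadjusted p = 0.00302). Its share of counts was 0.00578%, 0.000893%, 0.0123% and 0.000301% in BDE-209 libraries 1 to 4, against up to 0.00113% in controls. Without BDE-209 library 3 its log2 fold change was 2.57. The endothelial miR-126a-3p had a log2 fold change of 0.76 ± 0.26 and rose when adjusted over its list alone, with its partner arm miR-126a-5p at -0.48 ± 0.30. Of 6 neural microRNAs miR-9a-3p fell. Adjusted over that list alone, miR-9a-3p and miR-124-3p (-1.16 ± 0.34) fell and miR-128-3p (1.06 ± 0.29) rose. Of 7 leukocyte microRNAs none passed over all tested, and miR-223-5p (1.17 ± 0.33) rose over the list alone, with miR-146a-5p at -0.57 ± 0.25 and miR-146b-5p at 0.65 ± 0.28. The partner arm miR-223-3p, with 0.00459% of counts against 0.00162% for miR-223-5p, was at -0.72 (edgeR unadjusted p = 0.0720). Of 7 stromal and smooth muscle microRNAs 6 had lower means, with miR-199a-3p at -0.72 ± 0.39 and miR-143-3p at 0.61 ± 0.27. The 3 striated muscle microRNAs tested, among them miR-499-5p at 0.15 ± 0.23, did not pass, and their median of 0.15 and mean of -0.15 differed in sign. The erythroid miR-144 and miR-451, as well as miR-21 and miR-142, were listed at 0 counts in each of the 8 libraries, as were their genomic neighbours miR-193a, miR-365 and miR-301a, and no level is given for them.

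**Figure D3:**
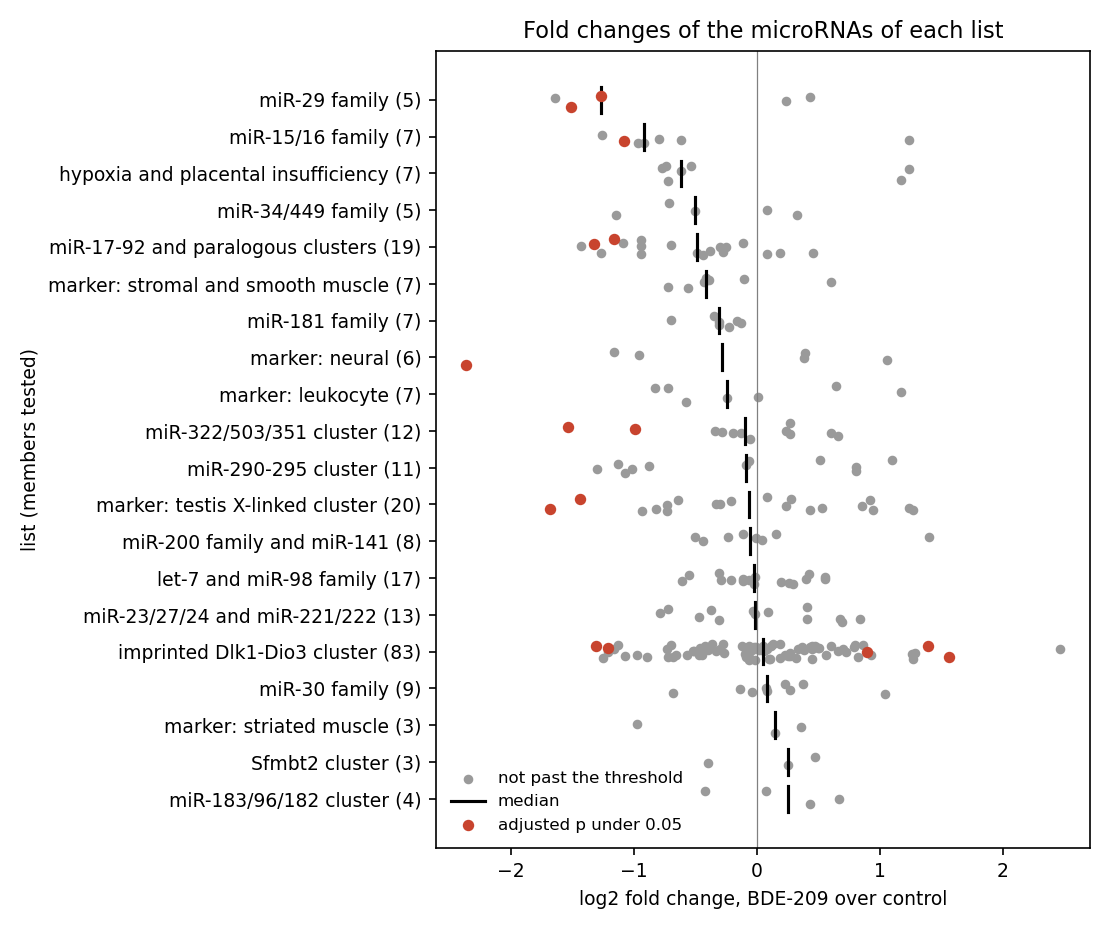
Log2 fold changes of the tested members of 20 lists, 1 point per microRNA on the horizontal axis, with the median as a black tick and the number of members in parentheses. Red points passed the threshold. The miR-29, miR-15/16 and miR-17-92 lists have medians of -1.27, -0.92 and -0.48, and the imprinted cluster has a median of 0.05.

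As shares of all counts, 0 of 22 lists passed (exact permutation test, Benjamini-Hochberg; 3 at an unadjusted p under 0.05). The X-linked cluster of miR-322, miR-503 and miR-351 took 11.1% ± 2.20 of control counts and 7.73% ± 1.24 of exposed counts (SD, n = 4, exact permutation p = 0.0286, adjusted 0.180). The miR-29 family took 0.212% ± 0.0652 and 0.0758% ± 0.0456, and the miR-15/16 family 0.189% ± 0.0447 and 0.0762% ± 0.0378 (SD, n = 4, exact permutation p = 0.0286 and adjusted 0.180 for each). The smallest p the design allows is 0.0286, and 13 of the 22 lists would have to reach it for any to pass. The imprinted cluster took 18.5% ± 1.99 and 19.4% ± 1.90, the let-7 family 14.0% ± 3.34 and 11.6% ± 1.85, and the male germ-cell cluster 3.00% ± 0.628 and 3.34% ± 0.361. For shares of stromal, endothelial, leukocyte and neural markers the exact permutation p-values were 0.829, 0.171, 0.0571 and 0.143, with adjusted values of 0.180 or above.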

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

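The test of a swapped pair of libraries, the comparison of library 4 with controls on the same microRNAs and the comparisons with other splits of the libraries were chosen after the results were seen. Those of a control library under an exposed label and of depth were fixed before their values were known.

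Of 212 groups of 4 libraries examined, 12 held a library whose gap to the nearest of the others took up most of the group's range (Dixon's ratio at its 95% critical value). Chance gives this in about 1 of 20 groups, or 10.6 here, and 6 of the 12 involved control library 2. In control library 2, miR-127-3p (42330 CPM), miR-146b-5p (455 CPM), miR-223-5p (5.59 CPM) and miR-676 (33.2 CPM) were the lowest of their group. miR-155-5p (502 CPM) and the let-7 share of counts (19.0%) were the highest there. Among other controls, miR-293-3p was high in library 1 (96.1 CPM) and miR-30e-5p low in library 4 (560 CPM). Among exposed libraries, miR-34c-5p (131 CPM) and the miR-30 share (5.36%) were high in library 1, miR-1-3p (95.7 CPM) in library 3, and the share of hypoxia-linked microRNAs (0.117%) in library 4.

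BDE-209 library 4 lay beside the controls in the principal components. The tables argue against a swap with a control library, since 0 of 4 controls correlated better with the exposed libraries than with the other controls, and against depth, since thinning each library to the smallest total moved its position by 0.0286. Its median position between the control mean (0) and the mean of the other exposed libraries (1), over the microRNAs called without it, was 0.267. Left-out controls lay at -0.258 to 0.269 over microRNAs called without both that control and library 4. There library 4 lay above each, the least apart being 0.338 against 0.269 for control library 3 (quartiles 0.150 to 0.458). Scored in the same way, BDE-209 libraries 1 to 3 lay at 0.503, 0.992 and 1.12, where library 4 lay below each, at 0.224 to 0.263. With 4 controls and the spread of their positions, a control library carrying an exposed label cannot be told apart from an exposed one. A weaker response of that placenta to BDE-209 stays open too, untested. After thinning to the smallest total, BDE-209 libraries 1 to 3 held 531, 528 and 523 known microRNAs, below each control. Library 4 held 557, above each control. The 10 most abundant microRNAs took 49.2%, 51.6% and 56.5% of counts in libraries 1 to 3, above each control, and 43.9% in library 4. Whether library complexity, rather than BDE-209, sets libraries 1 to 3 apart was not tested and cannot be told from these counts.

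For the 23 microRNAs past the threshold, the 8 libraries were split into groups of 4 in each of 35 ways. Of these splits 1, the real one, gave as many calls, and the highest of the others gave 6. This does not exclude chance, since 1 of 35 is the smallest share the design allows and the comparison was chosen after the results were seen. At an unadjusted p under 0.05 the margin was small, with 31.6% of the tested microRNAs in the real split and 28.7% in the split that exchanges control library 3 with BDE-209 library 4. For the miR-17-92 list, 21 of the 35 splits gave at least 1 list past the threshold and the highest other gave 5, so chance cannot be excluded for the list.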

How the results depend on the processing

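Library sizes without the most abundant microRNA, known microRNAs alone, thinned counts and sample weights were chosen after seeing the data, and the other settings before. The counts depended on the setting, and in the main fit the edgeR adjusted p-values of the 23 lay between 0.0475 and 0.0485. The signs of the 23 did not reverse in any setting run, leave-one-out included, while 83 of 315 values under settings that kept the 8 libraries missed the threshold. Total-count scaling and no filter gave 0 calls by edgeR (23 higher and 120 lower, and 211 in all, at an unadjusted p under 0.05), against 119 by DESeq2 (62 rose, 57 fell; 22 of the 23 kept) and 24 by limma-voom (18 kept). Robust edgeR fitting gave 4, of which 0 rose and 4 fell. A mean of at least 10 CPM gave 45 calls (25 rose, 20 fell), upper-quartile scaling 31 (17 rose, 14 fell), known microRNAs alone 60 (34 rose, 26 fell) and sample weights 92 (41 rose, 51 fell). Without 1 library 0 to 67 rose and 0 to 66 fell. They were 67 and 66 without BDE-209 library 4, with each of the 23 kept, and 0 by edgeR without any other (108 to 168 at an unadjusted p under 0.05). DESeq2 size factors, collapsed predicted microRNAs, library sizes without the most abundant microRNA and thinning gave 23, 24, 23 and 19. Why the counts differed between settings was not tested.

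The replicate numbers did not pair the libraries: same-numbered libraries had correlations of their deviations of 0.0960, 0.0373, 0.251 and -0.172, and not each library correlated best with its own number. With a replicate block 34 were called, 11 that rose and 23 that fell, and 17 of the 23 were kept.

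The miR-17-92 list was down in 23 of 23 alternatives and past the threshold in 19. The count of lists past camera was 0 with sample weights and with an estimated correlation, as was that past fry for a shared direction, while fry for change in either direction passed 10 of 20. By camera it was 0 to 1 without 1 library, 0 without control library 4. Shares of counts gave 0 lists in each setting run, which says little of stability, since 13 of 22 lists would have to reach the smallest possible p for any to pass. The planned settings for normalised values alone were not run.

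Reversals of sign occurred in microRNAs and lists that had not passed. With total-count scaling log2 fold changes became -0.16 for let-7f-5p, -0.14 for miR-1-3p, -0.027 for miR-183-5p, -0.32 for miR-200b-3p, -0.22 for miR-25-3p, -0.11 for miR-26a-5p, -0.011 for miR-29b-3p, -0.20 for miR-450b-5p, miR-466b-5p and miR-499-5p, and -0.16 for miR-7a-5p. This scaling moves the median to -0.44. With upper-quartile scaling they became 0.078 for miR-27b-3p, 0.041 for miR-293-5p, 0.072 for miR-30c-5p and 0.033 for miR-450a-5p. With known microRNAs alone they were 0.021 for miR-27b-3p and 0.015 for miR-30c-5p, and with sample weights -0.021 for miR-200b-3p and 0.0028 for miR-450a-5p. Without 1 library they ranged from -0.18 to 0.024 for let-7g-5p, -0.095 to 0.74 for miR-1-3p, -0.34 to 0.035 for miR-181a-5p, -0.090 to 0.23 for miR-200b-3p, -0.23 to 0.13 for miR-27b-3p, -0.32 to 0.10 for miR-293-5p, -0.23 to 0.069 for miR-30c-5p and -0.19 to 0.074 for miR-450a-5p. The lists that turned had camera adjusted p-values of 0.966 (let-7, total-count scaling), 0.872 (leukocyte, mean of at least 10 CPM), and 0.830 and 0.956 (striated muscle, no filter and thinned). Without 1 library camera adjusted p-values ranged from 0.681 to 0.996 for Sfmbt2, 0.816 to 0.996 for leukocyte, 0.728 to 0.996 for neural, 0.873 to 0.996 for striated muscle, 0.743 to 0.996 for germ-cell, 0.744 to 0.998 for miR-200 and 0.474 to 0.996 for miR-290 lists. Differences of share, in percentage points, ranged from -0.520 to 0.686 for miR-290, -0.120 to 0.651 for miR-30, -0.191 to 0.173 for the miR-183 cluster and -0.208 to 0.674 for stromal lists.

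Depth limits microRNAs near 0.177 to 0.406 CPM, the level of 3 counts, most in BDE-209 library 2 with 7392692 counts.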

Other observations

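The microRNAs of the next paragraph, and the tests of hairpin arms, of the imprinted cluster's spread, of genomic order and of liver microRNAs, were chosen after values were seen. The test of neighbouring genes and that of the scaling factors were fixed before theirs were known.

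Of the family of miR-99 and miR-100, which represses the growth kinase Mtor, the 4 tested arms had higher means after BDE-209, while miR-99a-3p and miR-100-3p had too few counts to be tested. Log2 fold changes were 1.06 ± 0.33 (SE) for miR-99a-5p, 0.95 ± 0.30 for miR-99b-5p, 0.92 ± 0.25 for miR-99b-3p and 0.67 ± 0.31 for miR-100-5p, with edgeR adjusted p-values of 0.0699, 0.0699, 0.0576 and 0.157 (Benjamini-Hochberg), so none passed. The epithelial miR-205 averaged 837 ± 253 CPM in controls and 423 ± 101 CPM after BDE-209 (log2 fold change -0.98 ± 0.29, edgeR adjusted p = 0.0662). miR-184 averaged 128.7 ± 63.3 and 296.8 ± 77.3 CPM (1.20 ± 0.33, edgeR adjusted p = 0.0563). From imprinted growth genes, miR-675-5p and miR-675-3p, cut from the H19 transcript, had log2 fold changes of -0.63 ± 0.24 and -0.17 ± 0.26, and miR-483-5p and miR-483-3p of Igf2 had 0.42 ± 0.20 and -0.56 ± 0.27, with edgeR adjusted p-values from 0.0997 to 0.676.

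Of 172 hairpins 84 had arms of opposite sign, as did 7 of the 20 with both arms at an unadjusted p under 0.05, and members of the imprinted cluster also differed in direction. The fold changes of the 5p and 3p arms had Pearson r = 0.0897 (permutation p = 0.240) and Spearman rho = 0.0759 (permutation p = 0.324). In the 107 hairpins with at least 10 CPM in both arms r was 0.0711. The arms thus showed no correlated change across hairpins, which are not independent replicates. These correlations restate the opposed signs and are not separate evidence against arms moving together. Neighbouring genes did not move together beyond shuffled ones either (16 neighbourhoods, mean SD of fold changes 0.523 against 0.541, one-sided permutation p = 0.328). In the imprinted cluster at least 6 members lay on each side at an unadjusted edgeR p under 0.05 under each of 4 scalings. Opposed directions thus remained under each scaling, but which side held more members depended on it. Whether a shared transcriptional change underlies the imprinted cluster cannot be told apart from its absence, since the SD of its fold changes was 0.969 times that of other known microRNAs, where 95% of random lists of its size gave 0.804 to 1.26. Error in fold changes from 4 libraries per group could also leave the signs of 2 arms unrelated. A change in the stability or loading of single arms may be at work as a hypothesis, as may cross-mapping of similar sequences. None of these was tested.

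Among 270 hairpins with both arms listed, 15 had 0 counts in the 8 libraries, and 7 of these were consecutive in the genomic order of GRCr8: miR-144, miR-451, miR-193a, miR-365, miR-21, miR-301a and miR-142. None of 10000 shuffled orders had a run of more than 4 (permutation p = 0.0001, the smallest they can give), but over all 442 placed hairpins, tested before the restriction to both arms, the longest run was 4 (p = 0.339). Since the restriction followed that result, 0 counts falling without regard to genomic order cannot be told apart from a shared cause. Loss of each microRNA of the stretch before deposit is argued against by the 2 of its 17 that held counts, 410 for miR-3549 and 2 for miR-632. A loss of some of them in the authors' mapping or counting stays open as a candidate explanation. Absence from the tissue was not tested, and the listed 0 counts do not show it. The shares of all counts, and the erythroid, leukocyte and hypoxia lists, therefore hold no reads of these microRNAs.

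The higher mean of the hepatocyte microRNA miR-122-5p might reflect liver RNA carried in maternal blood, and such maternal liver RNA in the placenta cannot be told apart from its absence here. Of miR-192-5p and miR-194-5p, also abundant in liver, 0 rose at an unadjusted p under 0.05 (edgeR log2 fold changes 0.53 ± 0.25 and -0.56 ± 0.23), but control levels of 383 and 269 CPM could hide an addition the size of that of miR-122-5p, from 4.26 to 67.4 CPM. The log2 fold change of miR-122-5p was 2.57 without BDE-209 library 3.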
